A study of Mus musculus with 19 samples.

How the data were processed

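Small RNA from the right hippocampus of adult male C57BL/6 mice was measured on 19 miRNA arrays in 5 groups. Per the labels' protocols, total RNA was extracted with TRIzol, low-molecular-weight RNA was isolated by ultrafiltration, and its 3' ends were labelled with the Oyster-550 dye. The arrays therefore had 1 colour. The labels describe an array platform although the protocol text also says that RNA was sequenced, and the values analysed here were array values. The groups were vehicle-treated control (n = 4), siRNA against GSK3b (siGSK3b, n = 4), the GSK3 inhibitor L803mts (n = 4), lithium (n = 4) and ketamine (n = 3). The labels give each sample its own replicate number but do not state that each came from a separate mouse, so the p-values measure the spread between these samples.

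Per the file headers, the deposited scanner values were GenePix Pro intensities of 1 channel on a linear scale, with no normalization by the scanner software. Each deposited intensity file covered a whole slide of 4 arrays in 32 blocks, files of samples on the same slide held the same values, and the labels name the 8 blocks that belong to each sample. Only those blocks were used, and 5 arrays of the 6 slides that belong to no sample analysed here were left out. A labelled spike-in spot, bright in array positions A and C (mean intensity 12588 to 30265) and near background in positions B and D (107 to 123), had the pattern that the assigned positions give. The authors' deposited table of processed values for 747 probes was also on a linear intensity scale. Its 4778 cells with 3 decimals were values of 1000 or more whose digit-grouping comma stood as a decimal point. After that was reversed, each column's correlation across probes with its own array's background-subtracted intensities was at least 0.99970, against at most -0.50 before it. The authors' columns differed from the scanner intensities by a factor of 0.779 to 1.58 per array, and their medians ran from 315 to 352. The authors' normalization method is not given in the sources used here. The scale and direction of that table were settled by this comparison, while whether a centring step entered is unknown.

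Local background medians were subtracted from foreground medians with the normexp method and an offset of 50 in limma 3.58.1 under R 4.3.3, and files were read with version 1.17.8 of data.table. Values were put on the log2 scale, the 3 spots of each probe were averaged, spots flagged bad were left out, and arrays were quantile normalized. The 40 empty, blank and spike-in spots per array were left out after the background step. Of the 3432 probe identifiers, 3421 were tested, each with a mean foreground over local background of more than 2 background SDs on at least 3 arrays, and 3003 met this on all 19 arrays. The files had no background SD per spot. The SD was therefore taken over each array's local background medians, from their median absolute deviation, which departs from the planned per-spot value. The number of probes detected per array ran from 3239 to 3397, and the precision of each value is limited by the number of arrays.

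Group means were fitted over all 19 arrays with limma and moderated across probes with its empirical Bayes step. Each of the 4 treatments was compared with control and L803mts with siGSK3b. An F test asked for any difference among the 5 groups. P-values were two-sided and adjusted over the tested probes by the Benjamini-Hochberg method, separately in each comparison, with a threshold of 0.05. A probe was called changed past that threshold, and all adjusted p-values in the text are from limma. Correlations of fold changes and shared calls between treatments were set beside 100 simulations of unchanged groups that shared the control arrays and beside the values with the control arrays split. On simulated data with 200 probes changed by 0.5 log2 units among 3432, the steps recovered 86.0% in siGSK3b vs control, 86.5% in L803mts vs control, 88.0% in lithium vs control and 85.0% in ketamine vs control. With changes of 1 log2 unit they recovered 98.0%, 96.5%, 97.5% and 97.5% in that order. False calls were then 14, 23, 20 and 16 among 210, 216, 215 and 211 calls, each share above 0.05. With changes of 0.5 log2 units they were 13, 8, 8 and 6 among 185, 181, 184 and 176. Simulated noise was drawn independently for each probe and array, without differences between slides.

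Probes carry vendor codes, and the files and the reference gene table do not pair these codes with miRNA names. None of the non-numeric identifiers (0) matched the reference table. The species of each probe is likewise not given, so probes for other species could not be set apart. The 17 miRNA lists fixed before the data were examined, among them the cluster in an intron of Htr2c, could not be applied. The rule for named probes, fixed at the same time, took the largest rises and falls past the threshold whose treated arrays all lay on that side of the control mean. Its restriction to probes named as mouse miRNAs could not be met, and printed identifiers were limited to 2 that rose and 2 that fell, those that led the most comparisons. GSK3b mRNA was not measured by these arrays, so the knockdown was not checked here.

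The analysed arrays of each slide were of 1 group, and slide and treatment were thus confounded except that L803mts replicate 2 was the only analysed array of another slide. In the other groups the spread between samples was that between arrays of 1 slide. The p-values therefore leave out differences between slides, except through L803mts replicate 2. Per the file headers that slide was scanned on another day than the others. Serial numbers of the slides, from the labels, followed the order control, siGSK3b, L803mts, lithium and ketamine, and the slide of L803mts replicate 2 came 8 steps after that of its group. Slide was tried as a random block. Other alternatives were the background correction and its offset, the normalization, the filter on dim probes, spot flags, the foreground mean, the authors' values, the variance model, replicate number and array position as blocks, and each array left out in turn. Added after the data were examined were the authors' probes only, print block medians centred on each array, and slide serial number as a covariate. With group means fitted, the slope of that covariate rests on L803mts replicate 2 against its group. It therefore cannot show whether a trend along the other slides was removed.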

Results

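The 19 arrays measured small RNA of the mouse hippocampus after vehicle or 1 of 4 treatments, in a series on glycogen synthase kinase 3 (GSK3), a serine/threonine kinase. The series asks which miRNAs respond in common. Control mice received vehicle intranasally at 5 µL per nostril every other day for 3 days (n = 4). On the same schedule, siGSK3b mice received 10 µg of siRNA against GSK3b (n = 4) and L803mts mice 60 µg of a peptide inhibitor of GSK3 (n = 4), with 11 and 61 µg given in the labels of replicate 4 of these groups. Lithium, a mood stabiliser that inhibits GSK3, was given in chow for 4 weeks (n = 4), at 0.2% in the sample labels and 2% in the protocol text. Ketamine, an NMDA receptor antagonist, was injected intraperitoneally at 10 mg/kg, 24 h before collection (n = 3). Neither lithium nor ketamine had a control given by its own route among the samples analysed here.

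Median foreground intensity per array ran from 115 in L803mts replicate 2 to 190 in lithium replicate 1, over median local backgrounds of 78 and 118 in the same arrays. The number of saturated spots ran from 128 to 194. Of 10336 spots, 88 were flagged bad in ketamine replicate 1 and at most 2 in any other array. Pairs of arrays correlated across probes at a median of 0.995 within groups (27 pairs) and 0.993 between groups (144 pairs). Among the analysed arrays no slide held more than 1 group, so that slide and treatment cannot be told apart for siGSK3b, lithium and ketamine. L803mts alone spanned more than 1 slide, with replicate 2 on a later one. Probes are given by their array codes, since the files do not pair them with miRNA names.

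The comparison of siGSK3b with control asked which probes changed when GSK3b itself was targeted. Probe ORB_1210051, at 13.57 ± 0.24 (SD, n = 4) in control on the normalized log2 scale, rose by 1.44 log2 units (SE 0.26, adjusted p = 0.0327), or 2.71-fold. The siGSK3b arrays had an SD of 0.31 (n = 4), and 4 of 4 lay above the control mean. The 3 other probes past the threshold rose by 0.33 to 0.37 log2 units (SE 0.05 to 0.06, adjusted p = 0.0219 for each). No probe fell (0 of 3421), while 393 probes had an unadjusted p under 0.05 in limma, in either direction. Falls were called under other settings, with 5 rises and 15 falls when only control and siGSK3b were fitted, 0 and 1 with trend and robust moderation, 7 and 5 with array weights, 7 and 3 with cyclic loess, 4 and 6 with slide serial number as a covariate and 4 and 1 with block medians centred. Of the other named probes, ORB_0511275 differed by 1.06 log2 units (SE 0.35, adjusted p = 0.229) and 3142 by -0.65 (SE 0.30, adjusted p = 0.423), neither past the threshold, although the fit of control and siGSK3b alone called ORB_0511275 (adjusted p = 0.0129, range over alternatives 0.0129 to 0.442). The call of ORB_1210051 was lost in 6 of 8 fits that left out 1 array, those without control replicate 2, 3 or 4 or siGSK3b replicate 2, 3 or 4 (adjusted p = 0.0553 to 0.151), and under 4 other settings (range over all alternatives 0.00424 to 0.151). The count of 4 became 33 without control replicate 1, 1 without control replicate 4 or siGSK3b replicate 2, and 0 without control replicate 2 or 3 or siGSK3b replicate 3 or 4.

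In L803mts hippocampus 85 of 3421 probes changed against control, 21 upward and 64 downward. Probe 3142 fell from 9.98 ± 0.41 (SD, n = 4) to 8.40 ± 0.83 (SD, n = 4), a difference of -1.58 log2 units (SE 0.30, adjusted p = 0.00887), to 33.4% of control. Probe ORB_1112497 fell from 11.49 ± 0.30 to 9.93 ± 1.15 (SD, n = 4 each), a difference of -1.56 (SE 0.37, adjusted p = 0.0341). Upward, ORB_0511275 rose by 1.45 log2 units (SE 0.35, adjusted p = 0.0392) and ORB_1210051 by 1.36 (SE 0.26, adjusted p = 0.00887). All 4 L803mts arrays lay on the called side of the control mean for each of these probes. Replicate 2 lay apart from the others: ORB_1112497 was at 8.20 there and between 10.47 and 10.54 in the other 3. Without replicate 2 its difference was -0.98 (adjusted p = 0.000901) and that of ORB_0511275 0.95 (adjusted p = 0.0274). The call of ORB_1112497 was lost without control replicate 1, 2 or 3 (adjusted p = 0.0629 to 0.0986) and under 6 other settings (range over all alternatives 0.000901 to 0.417), and that of ORB_0511275 without any 1 of the 4 control arrays or L803mts replicate 3 (adjusted p = 0.0504 to 0.105) and under 5 other settings (range 0.00854 to 0.557). With only control and L803mts fitted, none (0) of the 4 probes passed, at adjusted p = 0.255 for ORB_0511275, 0.265 for ORB_1112497, 0.16 for 3142 and 0.0601 for ORB_1210051. Leaving out not-found spots also lost the call of 3142, at a difference of -1.28 (adjusted p = 0.0542). The median called fall was -0.65 and the median called rise 0.37, and 18 falls and 2 rises exceeded 1 log2 unit. The fit restricted to control and L803mts gave 20 probes, 18 of them shared with the 85, and the covariate of slide serial number gave 8, each among the 85. With that covariate none (0) of the 4 probes passed, at differences of 0.45 for ORB_0511275, 0.90 for ORB_1210051 (adjusted p = 0.255), -0.79 for 3142 (adjusted p = 0.22) and -0.41 for ORB_1112497. With median scaling 7 rose and 60 fell.

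In lithium hippocampus 80 probes changed against control, with 35 rising and 45 falling. Probe ORB_1210051 rose to 15.55 ± 0.54 (SD, n = 4), by a measured 1.98 log2 units over control (SE 0.26, adjusted p = 0.000883), a lower bound because at least 1 of its spots was saturated on 1 lithium array. Probe ORB_0511275 rose by 1.54 (SE 0.35, adjusted p = 0.0289), and 3142 fell to 8.48 ± 0.19 (SD, n = 4), a difference of -1.50 (SE 0.30, adjusted p = 0.0115). Each had 4 of 4 lithium arrays on the called side. The call of ORB_0511275 was lost in 6 of 8 fits that left out 1 array, those without control replicate 1, 2 or 4 or lithium replicate 1, 2 or 4 (adjusted p = 0.0602 to 0.0935), and under 3 other settings (range over all alternatives 0.00394 to 0.105). Slide serial number as a covariate, with a slope from L803mts replicate 2 alone, brought it to 0.79 and 3142 to -0.90. The latter was still past the threshold (adjusted p = 0.0476), which does not separate it from a trend along the slides. Probe ORB_1112497 differed by -1.29 (SE 0.37, adjusted p = 0.081), which did not pass here but did with cyclic loess, the fit of control and lithium alone, array weights and block medians centred (range over all alternatives 0.00629 to 0.213). The median called rise was 0.35 and the median called fall -0.64 log2 units, with 2 rises and 15 falls beyond 1 log2 unit. Median scaling gave 50 calls, 11 up and 39 down, cyclic loess 22 up and 60 down, and leaving out not-found spots 3 up and 48 down, while over the authors' probes alone rises outnumbered falls, 13 to 7. Without control replicate 2 the count was 44.

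In ketamine hippocampus 116 probes changed against control, 46 upward and 70 downward. Probe ORB_0511275 rose from 10.61 ± 0.21 (SD, n = 4) in control to 13.24 ± 0.18 (SD, n = 3), by 2.63 log2 units (SE 0.38, adjusted p = 0.000807), or 6.19-fold. ORB_1210051 was saturated on 2 of the 3 ketamine arrays, so that its measured rise of 2.37 (SE 0.28, adjusted p = 0.000114) is a lower bound. Probe 3142 fell to 8.06 ± 0.10 (SD, n = 3), a difference of -1.92 (SE 0.32, adjusted p = 0.00195), to 26.4% of control, and ORB_1112497 fell to 9.65 ± 0.11 (SD, n = 3), a difference of -1.84 (SE 0.40, adjusted p = 0.015). All 3 ketamine arrays lay on the called side for these 4 probes. The call of ORB_1112497 was lost without any 1 of the 3 ketamine arrays (adjusted p = 0.0509 to 0.0661) and with slide serial number as a covariate (0.0754, range over all alternatives 0.000867 to 0.0754). The median called rise was 0.35 and the median called fall -0.64. Median scaling gave 9 rises and 70 falls and leaving out not-found spots 2 and 59, and the count was 69 without ketamine replicate 1. The covariate of slide serial number gave 59, of which 45 were among the 116, and brought ORB_0511275 to 1.63, 3142 to -1.13 and ORB_1112497 to -0.69. Here too its slope came from L803mts replicate 2 alone, so these values do not separate ketamine from its slide.

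**Figure D1:**
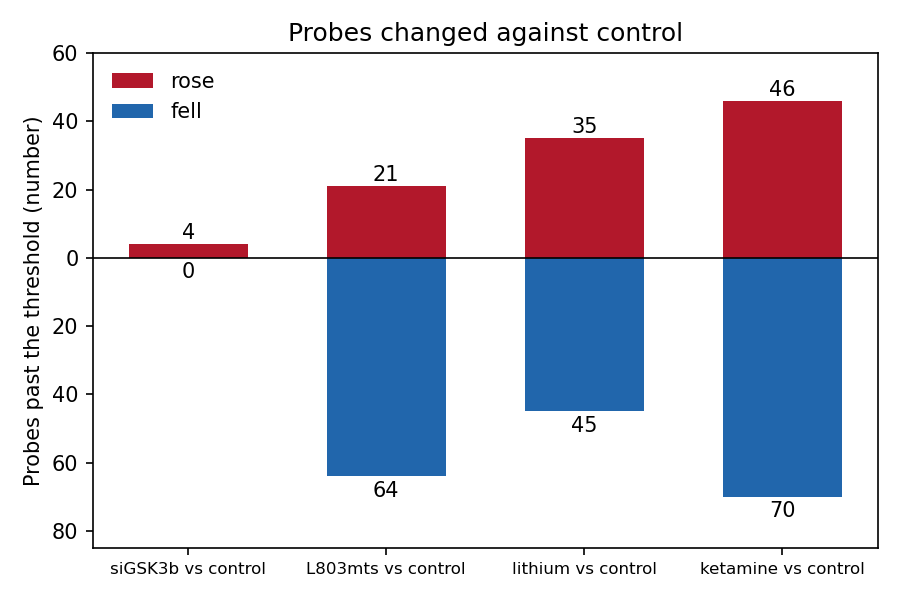
Number of probes past the threshold in each treatment against control (y axis, number of probes), with probes that rose above the zero line and probes that fell below it. Bars give 4 and 0 for siGSK3b, 21 and 64 for L803mts, 35 and 45 for lithium and 46 and 70 for ketamine.

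The common response was the next question. Of the 3421 probes, 3 changed in all 4 treatments, each upward. ORB_1210051 was one of them, and the other 2 rose by 0.33 to 0.34 log2 units in siGSK3b, 0.36 to 0.37 in L803mts, 0.30 to 0.34 in lithium and 0.40 to 0.56 in ketamine. The same 3 made up the set shared by siGSK3b, L803mts and lithium. In all, 173 probes changed in at least 1 treatment and 69 in 2 or more, and of those 69 none (0) changed in opposite directions. L803mts and ketamine shared 10 rises and 39 falls, where independent lists would share 0.282 and 1.31. Lithium and ketamine shared 15 rises and 35 falls against 0.471 and 0.921, and L803mts and lithium 12 and 36 against 0.215 and 0.842. All comparisons used the same control arrays, which independent lists leave out. In 100 simulations of unchanged groups sharing those arrays, none (0) gave a probe changed the same way in all 4, and a pair shared at most 0 rises and 1 fall. Those simulations in turn leave out any effects. They reshuffle deviations from group means, and the analysed arrays of each slide were of 1 group. Differences between slides therefore enter them only through L803mts replicate 2, and the simulated correlations below have the same limit. With the control arrays split, so that the treatments of a pair were compared with different control arrays, 6 such splits gave 3 to 6 shared rises and 10 to 23 shared falls for L803mts and ketamine, 3 to 7 and 5 to 22 for lithium and ketamine, and 0 to 5 and 5 to 10 for L803mts and lithium, from tests with fewer control arrays. For siGSK3b they gave 0 to 2 shared rises with L803mts, 0 to 3 with ketamine and 0 with lithium, and no shared falls (0), where siGSK3b itself had at most 4 calls. In these splits up to 2 probes changed in opposite directions in a pair. The control arrays were all on the same slide, so splitting them does not remove an effect of that slide. The split-control correlations below have the same limit. The set of 3 became 22 without L803mts replicate 2 and 0 without control replicate 2. With slide serial number as a covariate, its slope resting on L803mts replicate 2, 5 probes changed in all 4 treatments. None (0) of them was among the 3.

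Across probes, which are not independent replicates, log2 fold changes of siGSK3b and L803mts correlated at 0.77, against a simulated mean of 0.48 (95% of simulations from 0.16 to 0.74) from shared controls alone and 0.53 with the control arrays split. The lowest of the 6 pairs was siGSK3b with lithium at 0.32, against 0.47 simulated (0.16 to 0.78) and 0.13 with split controls. The other 4 pairs lay from 0.62 to 0.72, with split-control values of 0.38 to 0.50. Apart from siGSK3b with L803mts, each of these correlations lay within its simulated range, the upper end of which was 0.75 to 0.81 in those 4 pairs. That of siGSK3b with L803mts passed its upper end narrowly, and was 0.69 with plain background subtraction, 0.69 with slide serial number as a covariate, 0.67 without L803mts replicate 3 and 0.73 without siGSK3b replicate 4, all below 0.74. The observed covariance exceeded the simulated one in each pair, by 0.00527 in siGSK3b with lithium to 0.0259 in siGSK3b with L803mts.

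The F test found 132 probes differing among the 5 groups. L803mts against siGSK3b, which compared the inhibitor peptide with the siRNA, gave 0 probes past the threshold in limma, with 297 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0736. A p that misses the threshold does not show that these treatments acted alike.

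For the 2 named probes that fell, slide means followed the serial order of the slides. The 2 that rose departed from it: the mean of the siGSK3b slide lay above that of L803mts replicates 1, 3 and 4 for ORB_1210051 (arrays from 14.56 to 15.25 and from 14.37 to 14.96) and ORB_0511275 (from 11.49 to 11.84 and from 11.15 to 11.87), with overlapping arrays in both. L803mts replicate 2 lay below the mean of the ketamine slide for ORB_1210051 (15.61 and 15.94) and above it for ORB_0511275 (13.55 and 13.24). The arrays of 3142 lay between 9.54 and 10.50 in control, 8.99 and 9.55 in siGSK3b, 8.27 and 8.71 in lithium and 7.98 and 8.17 in ketamine, and L803mts replicate 2 lay at 7.21. For ORB_1112497 control arrays lay between 11.16 and 11.82 and ketamine arrays between 9.52 and 9.72. Comparisons between other pairs of treatments, chosen after the data were examined, gave 2 probes for lithium against siGSK3b, 15 for ketamine against siGSK3b, 0 for lithium against L803mts (297 at an unadjusted p under 0.05 in limma), 44 for ketamine against L803mts and 20 for ketamine against lithium.

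**Figure D2:**
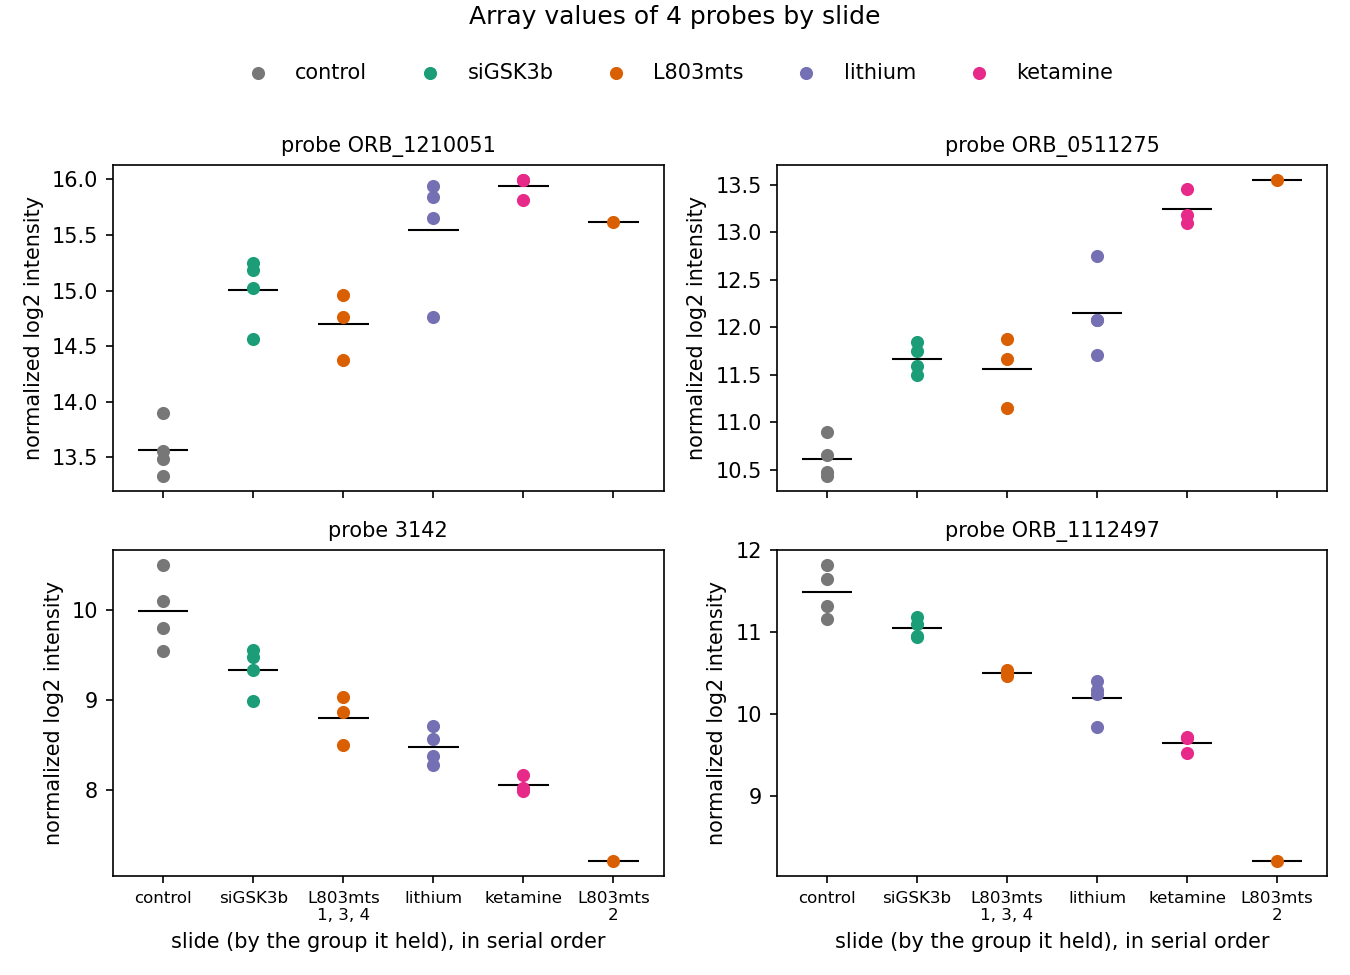
Normalized log2 intensity (y axis) of the 4 named probes on each array, by slide in serial order (x axis, slides named by the group they held); points are arrays and lines are slide means. Probe ORB_1112497 lies between 11.16 and 11.82 on the control slide and at 8.20 on the slide of L803mts replicate 2.

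The changed probes were unevenly spread over the array surface. Probes are printed in 8 blocks per array. Blocks 1, 2, 3 and 6 held 146 of the 173 probes changed in at least 1 treatment, or 84.4%, and 50.1% of the tested probes. These blocks were singled out after the counts were seen. Block 3 had the highest share changed (11.2%, 48 of 428) and block 7 the lowest (0.935%, 4 of 428). The chi-square over blocks was 96.9, with a permutation p of 1e-04, the smallest that 10000 permutations can give. That p treats probes as independent, although their calls come from the same arrays. It does not measure the spread between arrays or slides. Of the named probes, ORB_1112497 lay in block 1, 3142 in block 2, ORB_1210051 in block 3 and ORB_0511275 in block 7.

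**Figure D3:**
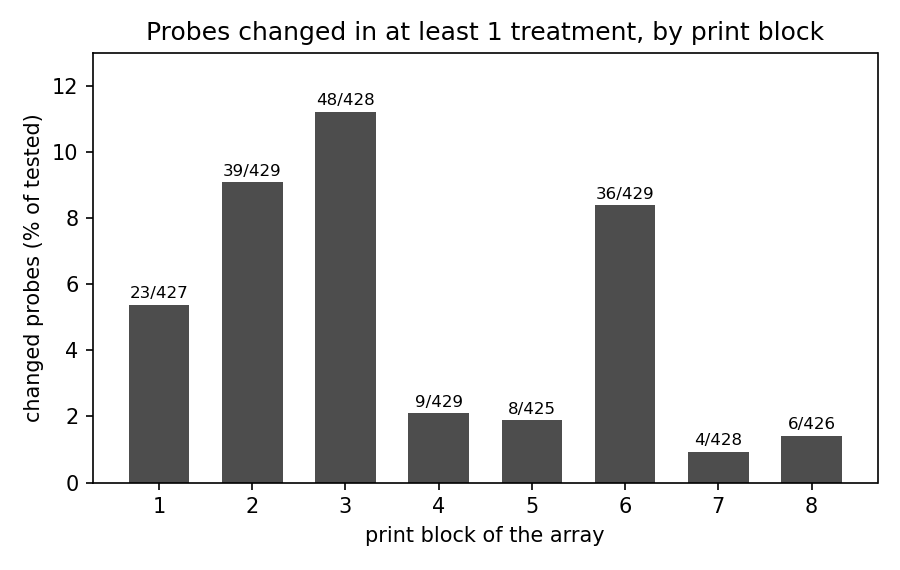
Share of tested probes that changed in at least 1 treatment (y axis, percent) in each of the 8 print blocks (x axis), with the number changed over the number tested above each bar. Block 3 is highest at 11.2% and block 7 lowest at 0.935%.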

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

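The counts over other splits of the arrays for the 4 treatments against control were planned; the other tests in this part were chosen after the results were seen. In L803mts, replicate 2 gave 8.20 for probe ORB_1112497, far below the 10.47 to 10.54 of the other 3 arrays. Array signal measures and the named probes were examined for such a gap in each group of 4 arrays. Of these 32 checks this was the 1 found, and chance alone gives about 1 in 20 (1.6 here). The checks share arrays and the probes were picked for large changes, so that number is only a rough guide.

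Chance division of the arrays was unlikely to give any of the counts against control. With 35 splits the smallest possible share is 1 in 35, and the 4 comparisons shared the control arrays, so they are not independent. Of 35 splits of the control and treated arrays, only the real one (1) reached the 4 probes of siGSK3b (highest other 0), the 85 of L803mts (highest other 33), the 80 of lithium (highest other 2) and the 116 of ketamine (highest other 20). Of 100 groupings of all 19 arrays, only the real one (1) gave as many as 132 probes in the F test (highest other 18), 3 changed in all 4 treatments (highest other 0) and 3 in siGSK3b, L803mts and lithium (highest other 0). For ketamine against lithium 2 of 35 gave the real 20 or more, with 26 as the highest other, so that chance division stays open there. For L803mts against siGSK3b the real count was 0, which all 35 splits reach by necessity (highest 2), so that they decide nothing. Since groups did not share slides among the analysed arrays, an unlikely chance division does not separate treatment from slide.

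Probes that fell between control and ketamine placed the other treatments in the serial order of their slides. Of the 65 such probes from those 7 arrays alone, 70.8% had siGSK3b, L803mts and lithium in slide order, with the L803mts mean taken over replicates 1, 3 and 4. The next most frequent order had 12.3%. Slide order held in 17.8% of the uncalled probes, and chance gives any order 16.7%. With replicate 2 included, the L803mts mean of 3142 was 8.40, below the 8.48 of lithium, and that of ORB_1112497 was 9.93, below 10.19. Of the 30 that rose, 30.0% were in slide order and as many (9) in another order. A trend along the slides is therefore a candidate explanation for the falls, and for the rises it stays open. Treatments of graded strength in the same order would give it too. L803mts replicate 2, on a later slide, lay further along than the mean of replicates 1, 3 and 4 in 147 of 197 probes called without L803mts arrays. Its median difference along the called direction was 0.194 log2 units. Replicate 4, on the group's own slide, lay further along than the mean of replicates 1 and 3 in 138, with a median of 0.066. These explanations remain open because the analysed arrays of each slide were of 1 group.

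L803mts replicate 2 stood apart from its group on probes that fell in other treatments. Over 108 such probes, called without any L803mts array, its median difference along the called direction was 0.397 log2 units, beyond each of the 18 other arrays (-0.14 to 0.104), while over 89 probes that rose it was 0.069, within their range (-0.063 to 0.084). Its slide may be the cause, since it lay further from control on the falling probes (0.73) than the ketamine slide (0.53 to 0.56), although a later slide that left rising probes in place is not what a trend common to both would give. The dimness of the array stays open: rising probes were 0.476 log2 units above falling ones after removal of its trend with brightness, but that trend spanned only -0.022 to 0.017 after normalization, so that removing it tested nothing. An animal that differs from its group cannot be told apart from the slide, as only 1 array analysed here was on it.

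Changed probes concentrated in print blocks 1, 2, 3 and 6. The tables argue against the identifier types and brightness of the probes in each block as the cause: with changed status permuted within both, the permutation p of the chi-square over the 8 blocks was 1e-04, the smallest that 10000 permutations can give, but what the probes target is unknown here, and responsive probes placed in these blocks stay open. They also argue against shifts of block medians between arrays as the whole cause, since with block medians centred these blocks held 82.1% of the 218 changed probes, and the counts were 94, 107 and 154 for L803mts, lithium and ketamine. Other differences between slides in those blocks may contribute: L803mts replicate 2 differed from its group by over 0.5 log2 units in 5.49% of probes in these blocks, which also held 169 of the 197 probes called without L803mts arrays, and in 2.34% elsewhere, a gap of 3.15 percentage points, where the 18 other arrays had gaps of -0.65 to 1.05. This rests on 1 array, and a treatment effect was not excluded. The permutation p above treats probes as independent, although their calls come from the same arrays.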

How the results depend on the processing

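The settings with only the authors' probes, with block medians centred and with slide serial number as a covariate were chosen after the data were examined; the others were planned. Over 304 values of the 4 named probes in the 4 comparisons, 275 stayed on their side of the threshold, 24 were no longer called, 5 became called and 0 reversed. Of 124 values with 1 array left out, 101 stayed on their side, 23 were no longer called and 0 reversed. The fixed miRNA lists and the Htr2c cluster were not run for want of probe names, and the alternative that tested probes of every species was identical to the setting used. The cause of the shifts below was not tested, except that fewer probes entered with the authors' table (747) and with not-found spots left out (2411).

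The counts for siGSK3b (4), L803mts (85), lithium (80), ketamine (116), all 4 treatments (3), the set shared by siGSK3b, L803mts and lithium (3, below the set without ketamine), the F test (132) and L803mts against siGSK3b (0) stayed within 1.5 times except as follows. Median scaling gave 1 for siGSK3b, 50 for lithium, 1 for all 4, 1 without ketamine and 73 for the F test. Cyclic loess gave 10 for siGSK3b, 5 for all 4 and 6 without ketamine. Plain subtraction gave 0 for siGSK3b, 0 for all 4, 0 without ketamine and 1 for L803mts against siGSK3b, where the offset of 16 also gave 1. Leaving out not-found spots gave 1, 7, 51 and 61 for the treatments, 1 for all 4, 1 without ketamine and 53 for the F test, with medians over all probes of -0.12 in lithium and -0.11 in ketamine. The authors' values gave 0, 10, 9 and 11, then 0, 0 and 36, and their probes with the values used here gave 0, 12, 20 and 11, then 0, 0 and 39. Trend and robust moderation gave 1 for siGSK3b, 1 for all 4 and 1 without ketamine, with none (0) of these among the 3. Fits of the compared groups alone gave 20 for siGSK3b and 20 for L803mts. Array weights gave 12 for siGSK3b, 8 for all 4 and 8 without ketamine. Array position as a block gave 2 for siGSK3b, 55 for L803mts, 1 for all 4 and 1 without ketamine. Serial number as a covariate gave 10, 8, 44 and 59, then 5 for all 4 and 5 without ketamine, with none (0) of these among the 3, and 74 for the F test. It brought each called difference of the named probes nearer to 0, such as ORB_0511275 in L803mts from 1.45 to 0.45. Its slope rests on L803mts replicate 2 alone. With block medians centred, 4 rose and 1 fell in siGSK3b and 35 rose and 59 fell in L803mts. In lithium 18 rose and 48 fell with only its own group and control fitted and 23 and 53 with trend and robust moderation. In ketamine 3 rose and 8 fell with the authors' values.

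Slide as a random block had a consensus correlation of 0.0158 and gave 4, 74, 63 and 100. With group means fitted, only L803mts spanned more than 1 slide. That correlation therefore rests on L803mts replicate 2 against its group and cannot show that differences between slides were small. The replicate number did not pair the samples: 10 of 36 same-numbered pairs correlated above 0.1 (median -0.02) and 6 of 19 arrays correlated best with their own number. The replicate block gave 4, 87, 75 and 107 probes for the treatments and 105 for the F test.

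Fold-change correlations moved by more than 0.5 times the width of their split-control range in siGSK3b with lithium, from 0.32 to 0.017 over the authors' probes; in L803mts with lithium, from 0.66 to 0.41 with the authors' values and 0.37 over their probes; in L803mts with ketamine, from 0.72 to 0.62 with the authors' values and 0.61 with serial number; and in lithium with ketamine, from 0.62 to 0.27 and 0.22 with the authors' values and probes.

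Leaving out each array in turn gave 0 to 33 probes for siGSK3b, 51 to 98 for L803mts, 44 to 68 for lithium, 69 to 119 for ketamine, 0 to 22 for all 4 treatments, 0 to 22 without ketamine, 80 to 179 for the F test and 0 to 0 for L803mts against siGSK3b. Without control replicate 2 the counts were 0, 51, 44 and 73, then 0, 0 and 82. For siGSK3b the count was 33 without control replicate 1, 0 without control replicate 3, 1 without control replicate 4, 1 without siGSK3b replicate 2 and 0 without siGSK3b replicate 3 or 4. Lithium had 49 without its replicate 2 and 49 without its replicate 3, and ketamine 69 without its replicate 1 and 72 without its replicate 2, where the F test had 80 without ketamine replicate 1. All 4 treatments, and the set without ketamine, had 8 without control replicate 1, 0 without control replicate 3, 1 without control replicate 4, 0 without siGSK3b replicate 2, 3 or 4, 5 without L803mts replicate 1 and 22 without L803mts replicate 2.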

Other observations

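On the 3 slides with all 4 arrays of a group, values were also compared between array positions. The value at position D minus that at position A had 1 sign on all 3 slides in 37.0% of the 173 changed probes and 29.5% of the 3248 others, where no position effect gives 25%. For 44 of the 173 that sign was the called direction, or 25.4%, where signs independent between slides give 12.5%. Probes are not independent, the unchanged ones also lay above 25%, and no test compared these shares. For 3142 the difference was -0.96 in control, -0.56 in siGSK3b and -0.44 in lithium. In the same order it was -0.67, -0.25 and -0.55 for ORB_1112497 and 0.57, 0.46 and 0.09 for ORB_1210051. For these probes the sign was the called direction on each slide, that of control included. For ORB_0511275, which rose, it was 0.17, 0.10 and -0.67. The treatments and the control held the same positions, except that L803mts replicate 2 was at position A and ketamine had no array at position D.

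The authors' deposited values covered 747 of the 3421 tested probes, and none of the 4 named probes (0) was among them.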
